A study of Mus musculus with 18 samples.

How the data were processed

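The series holds poly(A) RNA sequencing of the mouse embryonic stem cell line RHKI, an E14Tg2a derivative with a Dox-inducible HA-Rnaseh1 knock-in, in 6 groups of 3 libraries (day 0, day 3 and day 5, each with and without Dox). Its title concerns R-loops, the H2A.Z landscape and lineage allocation. Libraries were made with a stranded mRNA kit. The authors' processing notes name Trimmomatic, STAR 2.7.10a, RSEM 1.3.3 and DESeq2 1.38.2 with genome build GRCm38, but not the role or order of each, the annotation release, or the strand setting. The deposited RSEM gene tables hold expected counts, which are estimated counts per gene not scaled to depth, for 1 library per table. The deposited tables also hold TPM, used as an alternative for Rnaseh1 and Hprt, and FPKM, which was not used. Between 6.54 and 7.49% of the expected counts in a table were not whole numbers, and all were rounded for the count models. Each table lists 55401 gene IDs, and 55141 were matched to a symbol of GENCODE M21 without the version suffix (54349 with it). The 260 unmatched IDs held 0.0053% of the counts.

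Total counts per library ranged from 25748897 to 38128366. A floor of 3 counts per library was used for the lower bound of a fold change against a group without counts. Floors and the Wilson 95% interval of an rRNA share cover counting error only. A list's median over fitted fold changes was also taken with such genes at their bound. Over 126 lists and contrasts 6 medians moved by more than 0.1, the most by 0.55 (trophoblast at day 0, from -0.55 to 0).

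Counts were modelled in edgeR 4.0.16 (R 4.3.3) with quasi-likelihood F tests, TMM scaling (factors 0.894 to 1.063) and filterByExpr at its defaults (minimum count 10, minimum total 15), which kept 17795 genes. A fit of all 18 libraries had a mean per group, 12 residual degrees of freedom and a common biological coefficient of variation of 0.09. The contrasts were Dox against control at each day, the differences of these between days, and control day 3 against day 0 and day 5 against day 3. Benjamini-Hochberg adjusted p under 0.05 over all genes tested was the threshold. Fisher tests of shared calls were one-sided and adjusted over 12 pairs of directions. The p-values measure the spread between these samples, since nothing in the labels says that replicates are separate cultures. That spread was pooled per gene over all groups, but replicates differed more at day 0. The median chi-square per gene between 2 replicates of a group was 2.342 to 4.84 at day 0. It was 0.75 to 1.781 at day 3 and 0.819 to 2.189 at day 5. A pooled spread may be too small for day 0 and too large for day 3, so the counts of calls do not rank the days.

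The labels' batch tag equals the replicate number, so the numbers may pair samples. After the group means were removed, libraries of the same number correlated across genes at r of 0.206 to 0.331 at day 0 (other numbers -0.252 to 0.055), 0.01 to 0.036 at day 3 (-0.043 to 0.02) and 0.022 to 0.051 at day 5 (-0.057 to 0.02). Genes are not independent replicates here. The fit has no block, and a fit with the replicate number as a block is an alternative.

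The groups, tests, alternatives, 36 gene lists and the rule for naming genes were fixed before the data were examined. A further 7 lists (lysosome, retinoic acid metabolism and targets, Hedgehog targets, ventral and dorsal neural tube, cytosolic aminoacyl-tRNA synthetases and ribosome biogenesis) were chosen after the calls were seen. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01 and with an estimated correlation, with adjusted p over the lists within a contrast, and by counts of members past the threshold over all genes and adjusted over the list alone. In the lists that camera called in a Dox contrast, median, mean and test had the same sign. The symbols Dux, H2az1 and H2az2 are not in the annotation. Named genes were Rnaseh1, then for each Dox contrast the 8 higher and 8 lower genes with the largest log2 fold changes among those past the threshold, with at least 5 CPM in the higher group, a symbol that is not a placeholder and no overlap between the groups' libraries. For the control contrasts 5 and 5 were taken, and for differences between days 5 without the rule on overlap. From each list up to 4 members past the threshold with the largest changes were named, or where none passed the 2 with the highest mean CPM. Some genes that these rules select are not reported here. Genes compared between day 0 and day 5 were examples picked among the shared calls after their values were seen.

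Alternatives were the replicate block, DESeq2 1.42.0, limma-voom, RLE factors, library size alone, no filter, at least 1 CPM in 3 libraries, an absolute log2 fold change of at least 1, each day fitted alone with and without the block, and leaving out each library. Leaving out the rRNA gene CT010467.1 and repeating the list tests and shared calls without day 0 Dox replicate 2 were added after the data were seen.

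The fit was tested on simulated data with 200 changed genes. At a log2 change of 0.5 it recovered 55.2%, 52.2% and 55.2% of the changed genes at day 0, day 3 and day 5. At 1 it recovered 85.1%, 95.5% and 92.5%, and at 2 it recovered 100% at each day. Unchanged genes made up 13 of 173 calls at day 0, and 6 of 171 at day 3 and at day 5, among 17569 to 17604 genes run. Counts were drawn independently at the fitted spread. They held no structure by replicate number, no larger spread at day 0 and no library like day 0 Dox replicate 2. The simulation therefore cannot tell how these features affect the calls. No cells without the transgene were given Dox among these samples, so an effect of Dox itself cannot be separated from that of Rnaseh1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. In 2 of them genes were drawn from 0.1 CPM in a day 5 group, a limit chosen after the figures were seen.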

Results

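Poly(A) RNA was sequenced from mouse embryonic stem cells that carry an HA-tagged Rnaseh1 knock-in under doxycycline (Dox) control, before and during gastruloid differentiation. Gastruloids are aggregates of stem cells that form tissues of the early embryo in culture. The line, RHKI, was derived from E14Tg2a. Dox was given at 500 ng/ml for 48 h before differentiation, and the labels do not state whether it was continued. The 18 libraries fell into 6 groups of 3, which were Dox and control at day 0 (0 h), day 3 (72 h) and day 5 (120 h). The day 0 control libraries held 27654553, 35318785 and 28265284 counts, and the day 0 Dox libraries held 25748897, 28710172 and 29171102. Day 3 control libraries held 29132482, 38022886 and 38128366 counts, and day 3 Dox libraries held 32692650, 27302352 and 32408882. Day 5 control libraries held 28025314, 30424960 and 37393018 counts, and day 5 Dox libraries held 30926789, 31165047 and 32663682. Principal component 1 held 70.84% of the variance between libraries and component 2 held 22.04%, and both separated the days. Values below are CPM, library-size scaled counts corrected by TMM factors, as mean ± SD with n = 3 libraries. Log2 fold changes from edgeR are Dox against control of the same day. Gene positions are on GRCm38.

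Dox raised Rnaseh1, the gene for the nuclease that degrades the RNA strand of RNA:DNA hybrids (ENSMUSG00000020630, chromosome 12, 28649602 to 28659589), at each of the 3 days. The comparison asks whether the labelled induction is seen in the transcripts. At day 0 Rnaseh1 stood at 28.3 ± 2.3 CPM in control and 153 ± 18 CPM in Dox (SD, n = 3), a 5.39-fold difference. At day 3 it stood at 23.5 ± 1.1 and 68.1 ± 2.1 CPM, and at day 5 at 19.7 ± 0.37 and 57.1 ± 3.3 CPM, both 2.9-fold. The edgeR adjusted p was 4.1e-13 at day 0, 9.9e-10 at day 3 and 1.3e-09 at day 5. With the deposited TPM values the log2 fold changes were 2.47, 1.61 and 1.61. Each table holds 1 value per gene, so transcripts of the knock-in and of the native gene were not told apart.

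Hprt, which encodes a purine salvage enzyme (ENSMUSG00000025630, chromosome X, 52988137 to 53021659), rose at each of the 3 days, with larger fold changes than Rnaseh1. Its level went from 12.4 ± 0.84 CPM in control to 333 ± 42 CPM in Dox at day 0 (SD, n = 3), a 26.9-fold rise with an edgeR adjusted p of 7.8e-17. At day 3 it went from 20.1 ± 0.88 to 88.3 ± 2.2 CPM, 4.41-fold, with an edgeR adjusted p of 1.7e-11. At day 5 it went from 20.5 ± 0.59 to 199 ± 16 CPM, 9.69-fold, with an edgeR adjusted p of 1.4e-14. The 22 other tested genes within 1 Mb of Hprt had a median log2 fold change of -0.33 at day 0, 0.05 at day 3 and 0.11 at day 5.

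**Figure D1:**
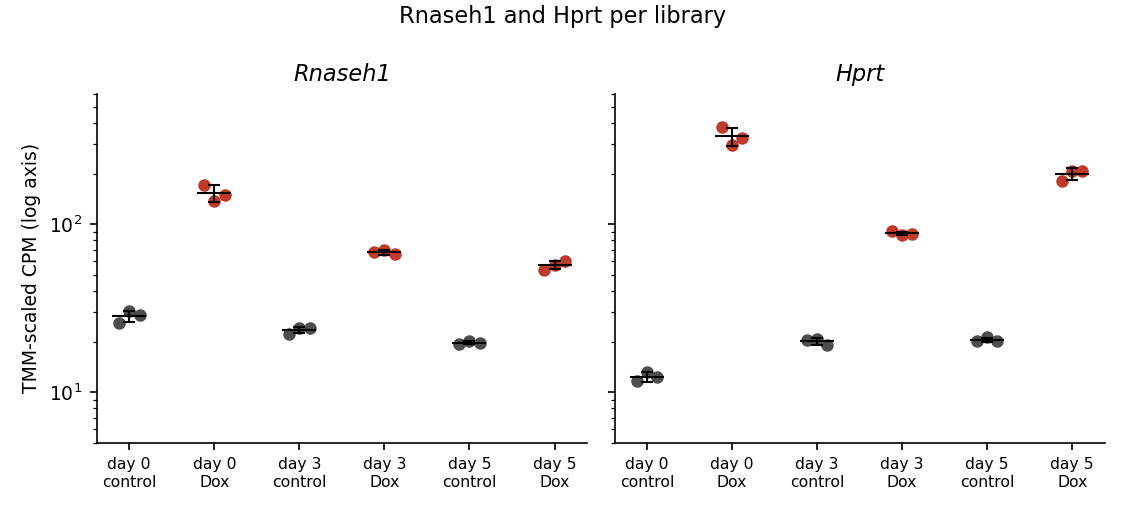
Level of Rnaseh1 and Hprt in TMM-scaled CPM on a log axis, with a point for each of the 18 libraries by day and Dox, a long bar at the mean and error bars of 1 SD (n = 3). Each Dox library lies above the control libraries of the same day, with Rnaseh1 at 153 CPM and Hprt at 333 CPM in Dox at day 0.

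Control cells lost naive pluripotency genes between day 0 and day 3, and T was among the genes that rose, which is the course against which the Dox effects are read. T, the transcription factor Brachyury of the primitive streak (chromosome 17, 8434423 to 8442496), went from 1.61 ± 0.97 to 604 ± 87 CPM (SD, n = 3), a 376-fold rise. Fgf8, a signalling ligand of the streak, went from 0.464 ± 0.21 to 90.5 ± 12 CPM, and Fgf5, a marker of formative pluripotency, from 0.359 ± 0.22 to 74.6 ± 9.9 CPM. Foxb1, a forkhead transcription factor, went from 0.0104 ± 0.018 CPM, a total of 1 count in 3 libraries, to 122 ± 6.7 CPM. Tcl1, a cofactor of the kinase Akt in naive cells, fell from 151 ± 15 to 0.0623 ± 0.025 CPM, and Sox2, a core pluripotency factor, fell from 456 ± 18 to 30 ± 0.61 CPM. Among genes without a count at day 0 the rise was at least 347-fold (Ccdc194), at least 195-fold (Ptn, a growth factor) and at least 150-fold (Rxrg, a retinoid receptor), against a floor of 3 counts per library. Genes without a count at day 3 fell at least 323-fold (Dppa3, a factor of naive cells and the early embryo), at least 276-fold (Osm, a cytokine), at least 265-fold (Fam25c) and at least 127-fold (Sash3, a lymphocyte adaptor). Crxos went from 70.3 ± 14 to 0.0111 ± 0.019 CPM, a total of 1 count at day 3.

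All 20 naive pluripotency genes fell in control cells between day 0 and day 3, with a camera adjusted p of 8.76e-57, and adjusted p = 1.39e-06 with an estimated correlation. Of the formative and primed genes 9 rose and 1 fell among 10, with a camera adjusted p of 9.91e-11, and adjusted p = 0.00632 with an estimated correlation. Of the primitive streak genes 8 rose and 3 fell among 11, with a camera adjusted p of 0.00282, and adjusted p = 0.234 with an estimated correlation. Of 17795 genes tested by edgeR, 6627 rose and 6455 fell, and 7726 rose and 5473 fell with library size alone as the scale. Rnaseh1 fell by 0.27 on the log2 scale in control cells, with an edgeR adjusted p of 0.0049. With that scale, which moved the median of all genes by 0.148 in this contrast, its change was -0.12 with an edgeR adjusted p of 0.2.

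Between day 3 and day 5, control cells gained neural, somite and Hox genes and lost most naive and core pluripotency genes and streak genes. Dbx1, a transcription factor of neural tube progenitors (chromosome 7, 49631499 to 49636849), had no count at day 3 and 367 ± 22 CPM at day 5 (SD, n = 3), at least 3680-fold higher. Fam181a rose at least 350-fold and Bmp3, a BMP family ligand, at least 197-fold. Hoxb5os, annotated as antisense to Hox genes, rose at least 488-fold, but whether the counting used the strand is not stated, so its level is uncertain. Pax6, a neural progenitor factor, went from 0.559 ± 0.092 to 262 ± 8.5 CPM, and Meox1, a somite factor, from 0.0196 ± 0.017 to 71.5 ± 6.7 CPM. Hoxd3 went from 0.0171 ± 0.015 to 130 ± 3 CPM, and Hoxb9 from 0.136 ± 0.04 to 245 ± 18 CPM. Pou5f1, which encodes the core factor Oct4, fell from 1130 ± 66 to 3.19 ± 1.2 CPM, and Nanog fell from 249 ± 12 to 1.22 ± 0.34 CPM. Evx1, a factor of the posterior streak, fell at least 126-fold, and Chrna9, an acetylcholine receptor subunit, at least 70-fold. Vrtn, which acts on the number of vertebrae, fell from 153 ± 8.5 to 0.103 ± 0.03 CPM, and Eomes, a streak factor, from 42.6 ± 14 to 0.0468 ± 0.041 CPM. Mixl1, a streak factor, went from 13.6 ± 5 to 0.00857 ± 0.015 CPM, and Foxi3 from 12.4 ± 1.4 to 0.0106 ± 0.018 CPM.

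Of the neural progenitor and neuron genes 17 rose and none fell among 20 in control cells between day 3 and day 5, with a camera adjusted p of 7.09e-24, and adjusted p = 0.000498 with an estimated correlation. Of the somite genes 12 rose and 1 fell among 14, with a camera adjusted p of 2.29e-09, and adjusted p = 0.000347 with an estimated correlation. Of the genes of Hox paralogues 6 to 9, 11 of 12 rose, with a camera adjusted p of 4.91e-14, and adjusted p = 0.000347 with an estimated correlation. Of 20 naive pluripotency genes 15 fell and 1 rose, with a camera adjusted p of 8.41e-11, and of 10 core pluripotency genes 7 fell and 1 rose, with a camera adjusted p of 7.62e-08, each with adjusted p = 0.00285 with an estimated correlation. Of the primitive streak genes 10 of 11 fell, with a camera adjusted p of 2.58e-12, and adjusted p = 0.00444 with an estimated correlation. Of 17795 genes tested by edgeR, 5637 rose and 5886 fell.

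At day 0, after 48 h of Dox in stem cell culture, a posterior transcription factor and a neuronal gene were among the genes that fell, and an enzyme of glutathione breakdown was among those that rose. The comparison asks what raised Rnaseh1 changes before differentiation. Cdx1, a homeobox factor of the posterior embryo (chromosome 18, 61018862 to 61036199), fell from 40.2 ± 12 to 12.8 ± 4.3 CPM (SD, n = 3), 3.15-fold, with an edgeR adjusted p of 0.00059. Nefm, a neurofilament subunit (chromosome 14, 68082590 to 68124846), fell from 62.8 ± 5.8 to 24.5 ± 4.9 CPM, 2.57-fold, with an edgeR adjusted p of 0.00018. The calcium-binding proteins S100a13 and S100a1 fell 2.53-fold and 2.1-fold, Pdzrn4 fell 3.05-fold, the protease inhibitor family gene Serpinb9b 2.51-fold, Patl2, an RNA-binding protein of oocytes, 2.47-fold, and Manba, a lysosomal mannosidase, 1.89-fold. Chac1, a glutathione-degrading enzyme of the integrated stress response (chromosome 2, 119351229 to 119354381), rose from 6.52 ± 2.1 to 18.1 ± 11 CPM, 2.75-fold, with an edgeR adjusted p of 0.037. Hhip, which binds Hedgehog ligands, rose from 6.26 ± 1.8 to 13.8 ± 2.5 CPM, 2.21-fold, with an edgeR adjusted p of 0.013. Pck2, a mitochondrial enzyme of gluconeogenesis, rose 1.74-fold, the collagen receptor Ddr2 1.83-fold, the muscle actinin Actn3 1.65-fold and the phosphatase inhibitor Ppp1r1a 1.61-fold.

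In total 52 genes were higher and 133 lower with Dox at day 0 by edgeR. With the replicate number as a block the count was 313, and a fit of the 6 day 0 libraries alone called 3 genes, or 137 with the block. It was 98 without control replicate 1, 303 without control replicate 3, 76 without Dox replicate 2 and 412 without Dox replicate 3. Dox replicate 2 held 4.76% of its counts (Wilson 95% interval 4.75 to 4.77%) in the rRNA gene CT010467.1, against 0.144 to 0.483% in the other 17 libraries. Without that library the edgeR adjusted p was 0.18 for Chac1, 0.065 for Hhip, 0.13 for Ddr2, 0.056 for Ppp1r1a and 0.086 for Manba. Without control replicate 1 the edgeR adjusted p was 0.14 for Chac1, 0.1 for Ddr2, 0.051 for Pck2, 0.072 for Ppp1r1a and 0.13 for Manba. It was 0.089 for Ddr2 without control replicate 2 and 0.073 for Chac1 without control replicate 3, and 0.064 for Chac1 in limma-voom.

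Among the fixed gene lists at day 0, calls were most frequent in the integrated stress response, through which cells raise amino acid synthesis genes. Of 18 measured stress response genes 6 rose and none fell, and 14 rose when adjusted over the list alone. Aldh18a1, an enzyme of proline synthesis, rose from 52.8 ± 4 to 82.7 ± 15 CPM (SD, n = 3), and Phgdh, an enzyme of serine synthesis, from 78.2 ± 5.5 to 116 ± 17 CPM. Mthfd2, a mitochondrial folate enzyme, had a log2 fold change of 0.64. The list's camera adjusted p was 3.43e-21, and adjusted p = 0.179 with an estimated correlation. Of 12 tailbud and neuromesodermal progenitor genes Cdx1 and Wnt5b fell, and 4 fell when adjusted over the list alone. The camera adjusted p was 0.000104, and adjusted p = 0.563 with an estimated correlation. Of 11 FGF and ERK targets Spry1 fell, and 4 fell when adjusted over the list alone. The camera adjusted p was 0.000366, and adjusted p = 0.568 with an estimated correlation. Without Dox replicate 2 the stress response list held 3 calls with a camera adjusted p of 4.15e-13, and adjusted p = 0.325 with an estimated correlation. The tailbud list then held 1 call with a camera adjusted p of 0.00161, and adjusted p = 0.605 with an estimated correlation. The FGF and ERK targets held no edgeR call, with a camera adjusted p of 1.21e-05, and adjusted p = 0.404 with an estimated correlation.

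Of 19 measured hypoxia and glycolysis genes at day 0, Pdk1, a kinase that inhibits pyruvate dehydrogenase, fell, and 4 fell and 1 rose when adjusted over the list alone. The camera adjusted p was 0.00389, and adjusted p = 0.631 with an estimated correlation. Of 11 Wnt targets Ccnd1, a cyclin, rose and Sp5, a Wnt-induced factor that is also on the streak list of 11 genes, fell from 32.6 ± 19 to 9.54 ± 7 CPM (SD, n = 3). The camera adjusted p was 0.0635 for the Wnt targets and 0.517 for the streak list. Id1 fell among 8 BMP targets, with a camera adjusted p of 0.261, and the DNA methyltransferase Dnmt3b fell among 10 formative and primed genes, with a camera adjusted p of 0.969. Without Dox replicate 2 the edgeR adjusted p was 0.15 for Sp5, 0.13 for Wnt5b, 0.12 for Id1, 0.13 for Spry1, 0.11 for Dnmt3b, 0.065 for Mthfd2 and 0.091 for Pdk1. Without control replicate 1 it was 0.16 for Sp5, 0.13 for Wnt5b, 0.17 for Id1, 0.072 for Spry1, 0.064 for Dnmt3b, 0.064 for Mthfd2 and 0.12 for Pdk1 by edgeR. Without control replicate 2 the edgeR adjusted p was 0.11 for Sp5, 0.055 for Wnt5b, 0.08 for Id1 and 0.11 for Spry1, and without control replicate 3 it was 0.052 for Dnmt3b and 0.072 for Spry1. Without Dox replicate 3 the edgeR adjusted p was 0.066 for Sp5, 0.11 for Id1 and 0.071 for Spry1, and without Dox replicate 1 it was 0.064 for Spry1. In limma-voom the adjusted p was 0.09 for Sp5, 0.087 for Wnt5b, 0.16 for Id1 and 0.068 for Spry1, in DESeq2 it was 0.06 for Sp5, and with the replicate block in edgeR it was 0.053 for Spry1.

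The replication-dependent histones, whose mRNAs lack poly(A) tails, had a median log2 fold change of 2.2 over 14 measured genes at day 0. No member passed the edgeR threshold over all genes, and 12 did when adjusted over the list alone. The list's camera adjusted p was 4.76e-05, and adjusted p = 0.631 with an estimated correlation. Without Dox replicate 2 its median was -0.073 and its camera adjusted p 0.963. A further 3 lists without an edgeR call lay higher by camera. The germline genes, 21 measured, had an adjusted p of 0.00351 by camera, and adjusted p = 0.595 with an estimated correlation. The p53 targets, 21 measured, had an adjusted p of 0.00352 by camera, and adjusted p = 0.652 with an estimated correlation. The mitochondrially encoded mRNAs, 13 measured, had an adjusted p of 0.00598 by camera, and adjusted p = 0.595 with an estimated correlation. Without Dox replicate 2 the germline list had a camera adjusted p of 0.14. In the 28 lists without an edgeR call at day 0, which hold 343 distinct measured genes, 49 genes had an unadjusted p under 0.05, DESeq2 called 5 and limma-voom called 2. These lists include naive pluripotency (camera adjusted p 0.986), core pluripotency (0.969), the H2A.Z histones and their remodellers (0.969) and the R-loop processing factors (0.564). The cell cycle list had a camera adjusted p of 0.0578, and of 0.0429 with RLE factors.

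At day 3, after 72 h of differentiation, 3 genes were higher with Dox and none lower by edgeR. The comparison asks how the Dox cells differ while streak genes are on. Besides Rnaseh1 and Hprt, Gm28438 rose from 108 ± 20 to 270 ± 21 CPM (SD, n = 3), 2.5-fold, with an edgeR adjusted p of 0.0048. It is an unprocessed pseudogene on chromosome 1 (24612775 to 24613119) next to other pseudogenes of mitochondrial genes, and whether it shares reads with them was not tested. It was singled out after its values were seen. An unadjusted p under 0.05 was found for 432 genes, DESeq2 called 5 genes higher and limma-voom 3. Leaving out day 3 control replicate 1 or 3 gave 2 calls. Other edgeR fits also called lower genes, with 14 higher and 11 lower without a filter, 9 and 3 in a fit of the 6 day 3 libraries alone, and 42 and 56 in that fit with the replicate block.

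No member of any of the 36 lists passed the edgeR threshold at day 3. Among their 435 distinct measured genes 28 had an unadjusted p under 0.05, DESeq2 called 2, both mitochondrially encoded, and limma-voom called 0. As a set the 11 primitive streak genes lay lower with Dox, with a median log2 fold change of -0.29 and a camera adjusted p of 4.78e-05, and adjusted p = 0.227 with an estimated correlation. The genes of Hox paralogues 1 to 5 lay lower by camera (adjusted p 0.0043), and adjusted p = 0.325 with an estimated correlation. Tailbud genes lay lower by camera (adjusted p 0.0259), and adjusted p = 0.433 with an estimated correlation. FGF and ERK targets lay lower by camera (adjusted p 0.0361), and adjusted p = 0.492 with an estimated correlation. Mitochondrially encoded mRNAs lay higher by camera (adjusted p 4.78e-05), with 3 of 13 past the threshold when adjusted over the list alone, and adjusted p = 0.227 with an estimated correlation. Naive pluripotency genes lay higher by camera (adjusted p 0.012), and adjusted p = 0.325 with an estimated correlation. Nodal and Activin targets had a camera adjusted p of 0.1, and of 0.0117 with the replicate block.

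At day 5, after 120 h, 426 genes were higher and 417 lower with Dox, and retinoic acid enzymes and Hox genes were among those with the largest changes. The comparison asks how the tissues formed differ with Dox. Cyp26b1, which degrades retinoic acid (chromosome 6, 84571414 to 84593908), rose from 1.89 ± 0.32 to 25 ± 9.4 CPM (SD, n = 3), 13.1-fold, with an edgeR adjusted p of 6.9e-08. Aldh1a2, which makes retinoic acid (chromosome 9, 71215789 to 71296243), fell from 13.6 ± 1.6 to 3.94 ± 1.6 CPM, 3.46-fold, with an edgeR adjusted p of 8.4e-05. Dhrs3, a retinaldehyde reductase, fell 4.5-fold. Slc44a5, a choline transporter-like protein, rose 4.04-fold, Msx3, a factor of the dorsal neural tube, 3.68-fold, Grm4, a glutamate receptor, 3.52-fold, and Atp1b2, a sodium pump subunit, 2.93-fold. Col12a1, a collagen, fell 4.98-fold, Foxe3, a lens factor, 4.91-fold, and Cabp1, a calcium-binding protein, 3.03-fold. The edgeR adjusted p of these 8 genes lay between 4.8e-08 (Slc44a5) and 0.00067 (Msx3), with 6.3e-07 for Cabp1. Hoxc8 (chromosome 15, 102990607 to 102994111) fell from 5.56 ± 0.81 to 1.6 ± 0.43 CPM and Hoxa7 (chromosome 6, 52214491 to 52221854) from 15.1 ± 2.9 to 4.94 ± 0.25 CPM. Hoxaas3, annotated as antisense in the Hoxa cluster, had a log2 fold change of -1.73, but whether the counting used the strand is not stated, so its level is uncertain.

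Of the 843 genes called at day 5 by edgeR, 186 changed by at least 1 on the log2 scale. The count was 519 without control replicate 2, 415 without control replicate 3, 468 without Dox replicate 2 and 410 without Dox replicate 3. A fit of the 6 day 5 libraries alone called 1628 genes, and DESeq2 called 1286.

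Hox genes of the middle of the clusters fell together at day 5. Of 12 measured genes of Hox paralogues 6 to 9, which pattern the trunk, 8 fell and none rose, and 9 fell when adjusted over the list alone. Their median log2 fold change was -1.11, with a camera adjusted p of 6.18e-23, and adjusted p = 1.28e-05 with an estimated correlation. DESeq2 called 6 of the 12 and limma-voom 8. In edgeR the call of Hoxc6 ended without each day 5 library in turn, and that of Hoxc9 without each but Dox replicate 3. Of 15 genes of Hox paralogues 1 to 5, which pattern hindbrain and neck, 6 fell and none rose, with 9 falling and 1 rising when adjusted over the list alone. The call of Hoxc5 among them ended in edgeR without any library of day 5 but Dox replicate 1. Hoxa5 fell from 23.7 ± 1.2 to 11.1 ± 1.3 CPM (SD, n = 3) and Hoxb5 from 17.6 ± 0.3 to 8.48 ± 1.1 CPM. In camera the list had an adjusted p of 3.87e-11, and adjusted p = 0.00705 with an estimated correlation. Of 8 genes of Hox paralogues 10 to 13 none passed in edgeR, DESeq2 or limma-voom, 0 had an unadjusted p under 0.05, and the camera adjusted p was 0.87. Hoxb13 stood at 0.119 ± 0.015 CPM in control and 0.0198 ± 0.017 CPM in Dox, and Hoxc13 at 0.0714 ± 0.022 and 0.0599 ± 0.0018 CPM. Counts were few at these levels, and whether a change could be detected there was not tested.

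**Figure D2:**
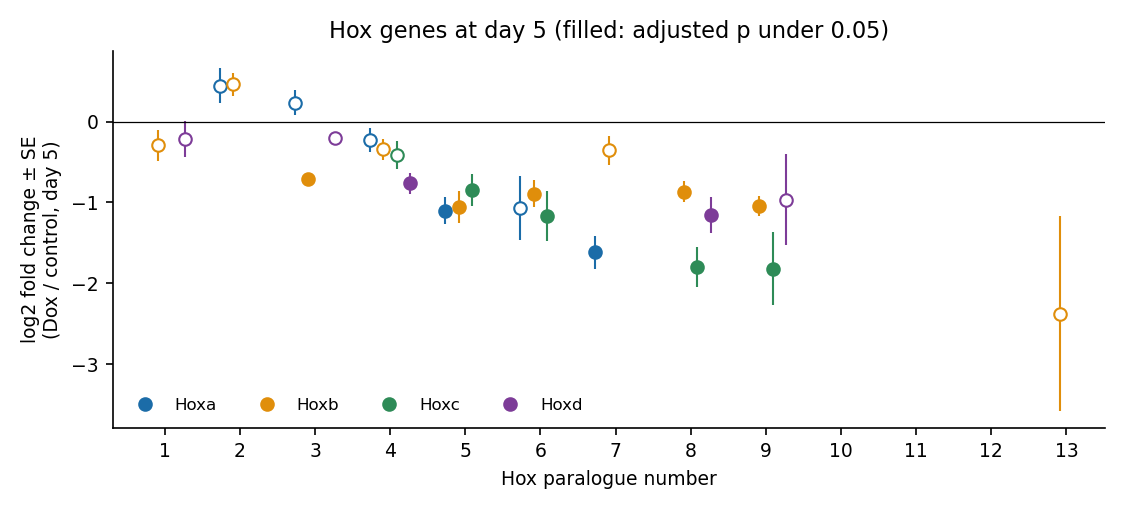
Log2 fold change of Hox genes, Dox against control at day 5, with its SE from edgeR, by paralogue number and cluster, for 26 of the genes with a mean of at least 0.1 CPM in a day 5 group. Filled points are those of the 26 with an adjusted p under 0.05, which number 13 and lie below 0.

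Somite genes fell with Dox at day 5. Pax1, a factor of the sclerotome (chromosome 2, 147361925 to 147393295), fell from 4.84 ± 0.27 to 0.547 ± 0.13 CPM (SD, n = 3), 8.79-fold, with an edgeR adjusted p of 4.4e-07. Pax3, a factor of the dermomyotome and of the dorsal neural tube, rose from 17.4 ± 1.6 to 29.5 ± 2.7 CPM, with an edgeR adjusted p of 0.0016. Of 14 measured somite and paraxial mesoderm genes 6 fell and 1 rose, and 8 fell and 1 rose when adjusted over the list alone. For this list the camera adjusted p was 8.98e-10, and adjusted p = 0.000315 with an estimated correlation. In the presomitic mesoderm list Pcdh8, a protocadherin, rose from 56.5 ± 0.84 to 109 ± 5.1 CPM, and Lfng, a modifier of Notch, had a log2 fold change of 0.3. Of the 9 measured 2 rose and none fell, with 3 rising and 1 falling when adjusted over the list alone. In camera the list had an adjusted p of 0.000823, and adjusted p = 0.064 with an estimated correlation. The call of Lfng ended without any library of day 5 but Dox replicate 1, with edgeR adjusted p of 0.091, 0.063 and 0.081 without control replicates 1, 2 and 3, and 0.16 and 0.13 without Dox replicates 2 and 3. The endoderm factors Foxa1, which fell from 3.89 ± 0.33 to 1.47 ± 0.19 CPM, and Foxa2, which fell from 1.78 ± 0.52 to 0.71 ± 0.095 CPM, were 2 of 9 measured definitive endoderm and gut genes. Of these 4 fell when adjusted over the list alone, with a camera adjusted p of 0.00016, and adjusted p = 0.00866 with an estimated correlation.

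Neural genes moved in both directions at day 5. Olig2, a factor of motor neuron progenitors (chromosome 16, 91225457 to 91228677), fell from 1.33 ± 0.39 to 0.178 ± 0.11 CPM (SD, n = 3), 7.36-fold, with an edgeR adjusted p of 0.0022. Neurog2, a proneural factor, fell from 13.1 ± 1.1 to 4.9 ± 0.99 CPM and Nkx6-1, a ventral progenitor factor, from 9.89 ± 0.94 to 4.45 ± 0.57 CPM. Elavl3, an RNA-binding protein of young neurons, rose from 14.4 ± 1.6 to 35 ± 5.3 CPM. Of 20 measured neural progenitor and neuron genes 3 rose and 4 fell, and 6 rose and 5 fell when adjusted over the list alone, with a camera adjusted p of 0.87. Its median was 0.18 and camera's direction was up, while more members fell than rose past the threshold over all genes. In the anterior neural plate list of 10 the forebrain factors Fezf1 and Fezf2 rose, with Fezf2 going from 1.04 ± 0.39 to 3.36 ± 0.54 CPM, while the list's median was -0.09 and its camera adjusted p 0.723. The call of Fezf1 held without Dox replicate 1, and its edgeR adjusted p was 0.16, 0.06 and 0.2 without control replicates 1, 2 and 3 and 0.17 and 0.2 without Dox replicates 2 and 3. In the neural crest list of 10, Tfap2b rose and Ets1 fell, with a camera adjusted p of 0.189. The edgeR adjusted p of Tfap2b was between 0.084 (without Dox replicate 1) and 0.13 (without control replicate 2) for each of the 6 libraries left out in turn. That of Ets1 was 0.072 without control replicate 1, 0.064 without Dox replicate 2 and 0.065 without Dox replicate 3 in edgeR.

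Of 21 measured p53 targets 11 fell with Dox at day 5 and none rose, and 14 fell when adjusted over the list alone. For this list the camera adjusted p was 2.17e-16, and adjusted p = 0.126 with an estimated correlation. Cdkn1a, the cell cycle inhibitor p21, fell from 119 ± 5 to 67.3 ± 5 CPM (SD, n = 3), 1.78-fold, with an edgeR adjusted p of 2.2e-06. Phlda3, an inhibitor of Akt, fell from 59.4 ± 1.6 to 32.7 ± 1.5 CPM and the kinase Plk2 from 38.4 ± 1.3 to 18.7 ± 0.41 CPM. In the integrated stress response list Asns, asparagine synthetase, went from 158 ± 12 to 103 ± 12 CPM at day 5 and Psat1, of serine synthesis, from 361 ± 17 to 242 ± 8.2 CPM. Of 18 measured 7 fell and none rose, and 9 fell when adjusted over the list alone, with a camera adjusted p of 2.76e-12, and adjusted p = 0.126 with an estimated correlation. Slc2a1, a glucose transporter, fell from 917 ± 57 to 605 ± 100 CPM. Of 19 measured hypoxia and glycolysis genes 6 fell and none rose, and 15 fell and 1 rose when adjusted over the list alone, with a camera adjusted p of 3.27e-08, and adjusted p = 0.127 with an estimated correlation. In edgeR the calls of Ldha and Pfkl ended without control replicate 2 or 3 or Dox replicate 2 or 3. That of Aldoa ended without control replicate 2 or Dox replicate 2 or 3. Of 13 mitochondrially encoded mRNAs 3 rose and none fell, and 4 rose when adjusted over the list alone, with mt-Cytb at 3610 ± 200 CPM in control and 4470 ± 91 CPM in Dox. In camera the list had an adjusted p of 0.00392, and adjusted p = 0.225 with an estimated correlation.

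**Figure D3:**
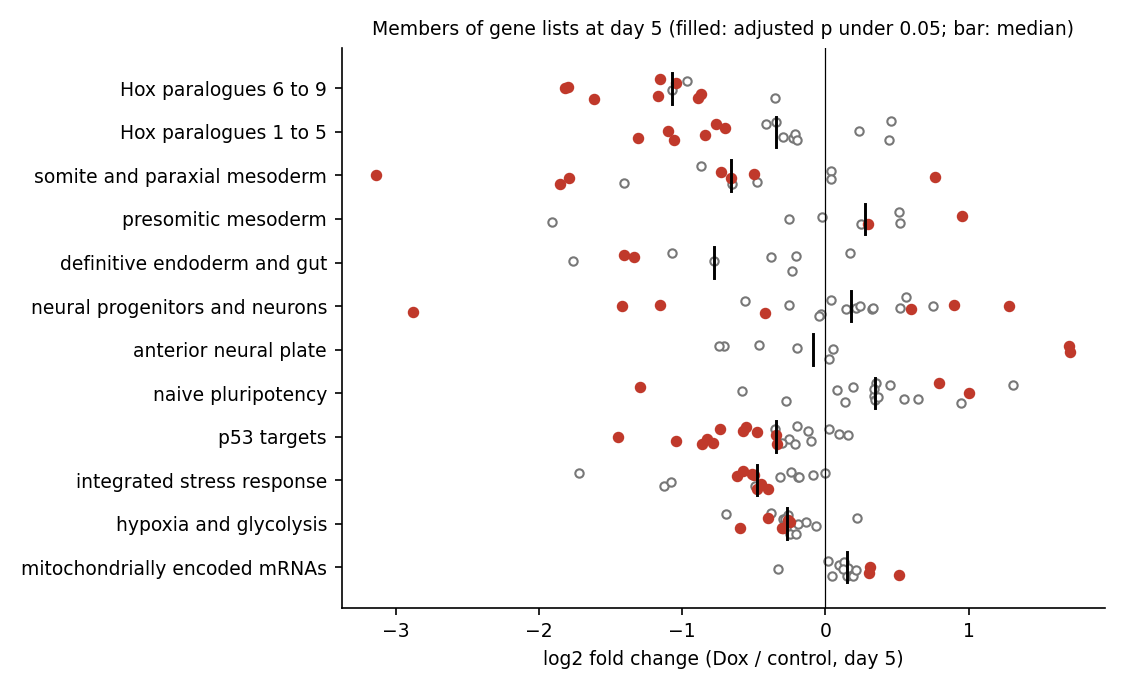
Log2 fold change, Dox against control at day 5, of the members of 12 gene lists with a mean of at least 0.1 CPM in a day 5 group, with filled points for an adjusted p under 0.05 and a bar at the median of the genes drawn. The medians drawn are -1.07 for Hox paralogues 6 to 9, -0.66 for somite genes, -0.35 for p53 targets and 0.15 for mitochondrially encoded mRNAs.

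Few pluripotency genes and signalling targets passed the threshold at day 5. Of 20 naive pluripotency genes Jam2, an adhesion molecule, rose from 9.79 ± 0.91 to 19.5 ± 2.3 CPM (SD, n = 3), Nanog from 1.22 ± 0.34 to 2.08 ± 0.49 CPM, and Tbx3 fell from 3.44 ± 0.56 to 1.41 ± 0.14 CPM. When adjusted over the list alone 2 rose and 2 fell. For this list the camera adjusted p was 0.0437, 0.05 with the replicate block, 0.0501 with RLE factors and 0.0692 with library size alone, and adjusted p = 0.329 with an estimated correlation. The edgeR adjusted p of Nanog was 0.052, 0.14 and 0.098 without control replicates 2 and 3 and Dox replicate 1, and 0.15 in limma-voom. Hes3, a transcription factor of the Hes family, rose from 96.3 ± 0.79 to 164 ± 12 CPM among 12 tailbud genes, while the list's median was -0.63. Of these 1 rose and 5 fell when adjusted over the list alone, with a camera adjusted p of 0.0384, and adjusted p = 0.387 with an estimated correlation. Of 11 FGF and ERK targets the factor Etv4 and the phosphatase Dusp6 fell, and 3 fell when adjusted over the list alone, with a camera adjusted p of 0.00874, and adjusted p = 0.329 with an estimated correlation. The adjusted p of Etv4 was 0.079 in limma-voom, and that of Dusp6 was 0.082 without Dox replicate 3 in edgeR. Ccnd1 rose among 11 Wnt targets, with a camera adjusted p of 0.87, and Id2 rose among 8 BMP targets, of which 2 rose when adjusted over the list alone, with a camera adjusted p of 0.196.

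Between 1 and 3 members passed in 5 further lists at day 5, none of which passed in camera. Sparc, a matrix protein, rose from 38.5 ± 3.2 to 65.3 ± 6.7 CPM (SD, n = 3) in the primitive and visceral endoderm list of 13, in which Dab2 rose and Lamb1 fell, with a camera adjusted p of 0.688. Tagln, an actin-binding protein, rose from 1.55 ± 0.38 to 3.41 ± 0.48 CPM in the fibroblast-type mesenchyme list of 10, in which the collagen Col5a1 also rose, with a camera adjusted p of 0.457. Tek, a receptor of endothelium, had 0.27 ± 0.041 CPM in control and 0.963 ± 0.36 CPM in Dox in the endothelium and blood list of 15, with a camera adjusted p of 0.46. Stat2 rose in the interferon and nucleic acid sensing list of 13, with a camera adjusted p of 0.937. Ruvbl2, an ATPase of several remodelling complexes, fell from 212 ± 9.3 to 183 ± 2.4 CPM in the list of 21 H2A.Z genes and remodellers, with a camera adjusted p of 0.87. The calls of 6 of these genes ended when 1 library was left out. In edgeR the adjusted p of Ruvbl2 was 0.19, 0.17, 0.13, 0.13 and 0.14 without control replicates 2 and 3 and Dox replicates 1, 2 and 3. That of Tek was between 0.051 and 0.095 for 5 libraries, the exception being Dox replicate 2, and 0.13 in limma-voom. That of Dab2 was 0.058, 0.11 and 0.14 without control replicates 2 and 3 and Dox replicate 3 in edgeR, and that of Lamb1 was between 0.13 and 0.19 without control replicates 2 and 3 or Dox replicates 2 and 3. That of Stat2 was 0.055 and 0.065 without control replicate 3 and Dox replicate 3, and that of Col5a1 was 0.068, 0.066 and 0.06 without control replicates 2 and 3 and Dox replicate 1 in edgeR.

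In 14 lists no member passed the edgeR threshold at day 5. Among their 140 distinct measured genes 29 had an unadjusted p under 0.05, DESeq2 called 7 and limma-voom called 2. Core pluripotency genes, 10 measured, lay higher by camera (adjusted p 0.0218), and adjusted p = 0.158 with an estimated correlation, with Pou5f1 at 3.19 ± 1.2 CPM in control and 4.58 ± 0.92 CPM in Dox (SD, n = 3). Cell cycle genes, 19 measured, lay lower by camera (adjusted p 0.00811), and adjusted p = 0.387 with an estimated correlation, with a median log2 fold change of -0.04 and 8 lower when adjusted over the list alone. The primitive streak and nascent mesoderm list of 11 had a camera adjusted p of 0.0849, and 0.0458 with library size alone, with T at 6.61 ± 0.96 and 3.88 ± 0.49 CPM and 3 lower when adjusted over the list alone. The formative and primed list of 10 had a camera adjusted p of 0.113, with 3 higher and 1 lower when adjusted over the list alone. The R-loop processing factors, 17 measured, had a camera adjusted p of 0.351, with Ddx5, a helicase, at 1030 ± 31 and 1020 ± 2.7 CPM. Camera adjusted p was 0.317 for cardiac and lateral mesoderm (13 measured), 0.613 for notochord and node (4), 0.87 for replication-dependent histones (14), 0.51 for germline genes (21), 0.438 for Nodal and Activin targets (7), 0.457 for trophoblast (5) and 0.69 for surface ectoderm (3). The two-cell-like list had 2 measured genes, too few for camera, and Zscan4f had 0 counts in control at day 5.

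**Figure D4:**
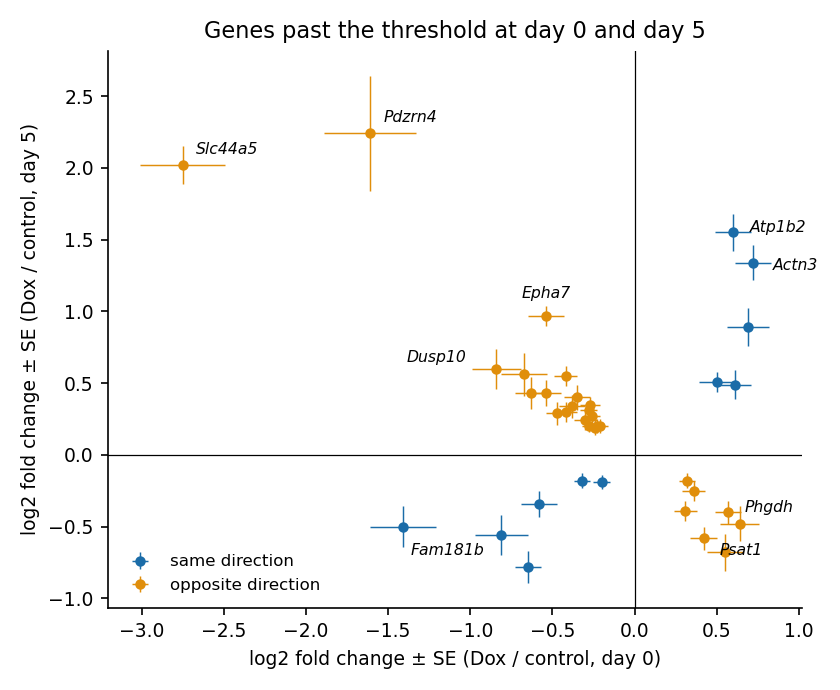
Log2 fold change with its SE from edgeR, Dox against control at day 0 (horizontal) and day 5 (vertical), for the 38 genes past the threshold at both days other than Rnaseh1 and Hprt. Points in the upper left and lower right are the 27 genes that moved in opposite directions, such as Slc44a5 at -2.75 and 2.02.

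Of the 133 genes that fell with Dox at day 0, 20 rose with Dox at day 5. Slc44a5 had log2 fold changes of -2.75 at day 0 and 2.02 at day 5, Pdzrn4 -1.61 and 2.24, Epha7, an ephrin receptor, -0.54 and 0.97, and Apoe, a lipid carrier, -0.67 and 0.56. Phgdh at 0.57 and -0.4, Psat1 at 0.42 and -0.58, and Mthfd2 at 0.64 and -0.48 went the other way. Actn3 at 0.72 and 1.34 and Ccnd1 at 0.61 and 0.49 rose at both days. Of the genes lower at day 0, 20 were higher at day 5, against 3.18 if the days were independent, with a one-sided Fisher exact test across genes giving an adjusted p of 6.73e-10. Of those higher at day 0, 7 were lower at day 5 against 1.22 and 7 were higher against 1.24, each with a Fisher adjusted p of 0.000678. The 7 genes higher at both days include Rnaseh1, which was induced by design, and Hprt. Of those lower at day 0, 6 were lower at day 5 against 3.12, with a Fisher adjusted p of 0.186, and 0.0494 with the replicate block. Genes are not independent replicates, and the days share no library. Without day 0 Dox replicate 2 the shared genes were 14 opposite and 8 in the same direction, against 27 and 13 with all libraries.

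The Dox effect itself was tested for a difference between days. Between day 0 and day 5 it differed for 584 genes, 313 with a higher and 271 with a lower effect at day 5 by edgeR, and Cyp26b1 had a difference of 4.18 on the log2 scale with an edgeR adjusted p of 0.00012. Between day 3 and day 5 it differed for 146 genes, 63 higher and 83 lower. Between day 0 and day 3 it differed for 10 genes, 7 higher and 3 lower, and the Rnaseh1 effect was smaller at day 3, with a difference of -0.89 and an edgeR adjusted p of 0.00087. The day 5 and day 0 count was 360 and 308 without day 5 control replicates 2 and 3, and 351 and 309 without day 5 Dox replicates 2 and 3. The day 5 and day 3 count was 70, 79 and 76 without day 3 control replicates 1, 2 and 3, and 86, 65 and 66 without day 3 Dox replicates 1, 2 and 3. It was 76 and 59 without day 5 control replicates 2 and 3, and 54 and 45 without day 5 Dox replicates 2 and 3. The day 3 and day 0 count was 35 with the replicate block, 52 without day 0 control replicate 3, 33, 6 and 43 without day 0 Dox replicates 1, 2 and 3, 6, 4 and 3 without day 3 control replicates 1, 2 and 3, and 6, 3 and 3 without day 3 Dox replicates 1, 2 and 3.

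Genes of the control course had median Dox effects near 0 at each of the 3 days. The question is whether the Dox effect lies along the course of differentiation, read on time contrasts that share no library with the Dox effect. At day 0 the 200 genes that rose most between day 3 and day 5 had a median Dox effect of 0.003 on the log2 scale and the 200 that fell most -0.02, with camera adjusted p of 0.717 and 0.644. At day 3 the genes that rose between day 0 and day 5 had a median of 0.025 with a camera adjusted p of 0.0198, and adjusted p = 0.362 with an estimated correlation, while those that fell had 0.019 with a camera adjusted p of 0.107. With the top 50 and top 500 genes the first of these had camera adjusted p of 0.103 and 0.0938. At day 5 the genes that rose between day 0 and day 3 had a median of 0.042 and those that fell 0.059, both with a camera adjusted p of 0.065.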

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

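Tests of the Hprt pattern, of library scaling and of day 0 Dox replicate 2 for the oppositely moving genes were chosen only after the result was seen, as was which splits count for the differences between days.

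Hprt rose with Dox at each of the 3 days, with log2 fold changes of 4.75, 2.14 and 3.28, larger than those of Rnaseh1. A rise of the whole X-chromosome region is argued against by the 22 other genes within 1 Mb, whose median at day 0 was -0.33. Library scaling is argued against by unscaled counts, in which the lowest log2 ratio of a Dox to a control library of the same day was 1.59, while library totals differed by at most 0.48 within a day. That the inducible transgene may sit in Hprt and its transcripts carry Hprt sequence stays open, since Hprt was raised by at least 2.14 at each day on which Rnaseh1 rose, but the insertion site is not in the labels and reads along the gene were not analysed here. E14Tg2a cells are known for an Hprt deletion, which is background and was not tested here.

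Of 40 genes called at both day 0 and day 5, 27 moved in opposite directions and 13 in the same, with Rnaseh1 and Hprt among the latter. For a single library, day 0 Dox replicate 2, the signs decide little. Of the 185 genes called at day 0, 181 had no overlap between Dox and control libraries. A sign could thus hardly change without 1 library, and 27 of the 27 kept theirs. Their median kept share of the change was 0.94. They were calls of a fit that held that library, so a large loss was also unlikely from the start. The share thus decides little, and a part of that library in the pattern stays open. Without day 0 Dox replicate 2 only 13 of the 27 were still called at day 0. Trends with GC content or length are argued against, as 27 of 27 kept opposite signs after these were removed, which moved a tested gene by up to 0.25. Library scaling is argued against as the whole cause, since a factor per library moves all genes of a day the same way, while 20 of the 27 fell and 7 rose at day 0, and the reverse at day 5. Differences between the day 0 cultures other than Dox stay open. Another split of those libraries shared at most 19 genes in 1 relation with day 5. This lay under a bound of 27, set before this test but taken from the genes already seen to move oppositely. That other split shared 7 in the other relation, so 73% lay in 1 relation against 68% in the real split. The split with 800 calls shared 15 and 13, those with 201 calls shared 6 and 5 and 5 and 1, and the real split shared 27 and 13 from 185 calls. That bound was no fair limit, as 4 of the 9 other splits called no gene at day 0 in edgeR and could share none. An effect of Dox itself cannot be told apart from that of Rnaseh1, since 0 of the 18 libraries came from cells without the transgene given Dox.

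Day 0 Dox replicate 2 held 4.76% of its counts in the rRNA gene CT010467.1 (chromosome 17, 39846353 to 39848827), and its replication-dependent histones stood at a median log2 ratio of 3.21 to the other day 0 libraries. The cell cycle list had a median log2 ratio of 0.09 in that library, with 15 of 19 genes higher. The median was also 0.09 in day 0 Dox replicate 1, whose histones stood at -1.46. The list holds genes of S phase and of mitosis, which could offset each other in a median. More cells in S phase therefore stay open. More RNA without poly(A) tails in that library stays a candidate cause that was not decided. There 6 of 6 small non-coding RNA genes stood higher, with a median log2 ratio of 4.66 to the other 5 day 0 libraries. These genes were kept at a mean of at least 1 CPM over the day 0 libraries, that one included. A gene could thus pass through that library alone, so their rise there was favoured by the choice. No biological explanation other than S phase was tested.

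The Dox effect differed between day 0 and day 3 for 10 genes, with 3 to 52 when 1 library was left out. The differences in log2 fold change were -2.61 for Hprt, 1.78 for Patl2, 1.29 for Nefm, -0.89 for Rnaseh1 and 0.59 for Mest, an imprinted hydrolase. The calls of Patl2, Nefm and Mest each ended without day 0 Dox replicate 2, with edgeR adjusted p of 0.072, 0.062 and 0.12, and without 5, 5 and 6 of the other libraries in turn, with edgeR adjusted p up to 0.16. Between day 3 and day 5 it differed for 146 genes, with 45 to 155 when 1 library was left out. The differences were -1.96 for Fgfr4, a growth factor receptor, -1.77 for Dhrs3, 1.77 for Slc44a5 and 1.68 for Grm4. The call of Fgfr4 had an edgeR adjusted p of 0.049, of 0.054 with the block, and of 0.076 to 0.22 without 11 of the 12 libraries in turn. That of Dhrs3 was 0.057 to 0.098 without 9 of the 12 libraries in turn, and that of Grm4 was 0.051 to 0.065 in edgeR without day 3 Dox replicate 2 or 3, day 5 control replicate 3 or day 5 Dox replicate 3. Between day 0 and day 5 it differed for 584 genes, with 308 to 795 when 1 library was left out. The differences were 4.77 for Slc44a5, -4.3 for Nlrp4a, 4.18 for Cyp26b1, 3.85 for Pdzrn4, 3.38 for St8sia2, a sialyltransferase, and -0.89 for Rnaseh1. Nlrp4a was near 0 at day 5, and its call ended in DESeq2 (adjusted p 0.058) and without 9 of the 12 libraries in turn (edgeR adjusted p 0.05 to 0.15).

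Other splits of the libraries were counted for each number of calls. For the 3 Dox contrasts and the 2 control contrasts the 10 splits are too few for a share under 0.05. The real split called 185 genes at day 0 and the highest other 800, and 5 of the 10 called as many, the real one included. That split puts control 1, Dox 1 and Dox 2 together and parts 1 pair of replicate numbers. The 6 splits that part 1 pair called 800, 354, 201, 201, 54 and 0, and the 3 other splits that part all 3 pairs called 0. The day 0 libraries thus have a structure that follows the replicate numbers in part. With the replicate block the real split called 313. At day 3 the real split called 3 and at day 5 it called 843, and the highest other split called 0 at each, so 1 split, the real one, called as many. The control contrasts called 13082 and 11523, and the highest other split called 0. For the differences between days, 24 of the 200 splits within days were drawn. A split that keeps or exchanges the whole groups of 1 day carries the Dox effect of that day, so it says nothing about chance and is not counted. For day 3 and day 0 this left 19 splits and for day 5 and day 3 it left 18, both too few for a share under 0.05. In the first the real split called 10 and the highest other 7, and in the second they called 146 and 0, so 1 split, the real one, called as many in each. The splits not counted called up to 11 and 251. For day 5 and day 0 it left 22, of which 2 called at least the 584 of the real split, with 846 as the highest other, so chance cannot be excluded by this count. That other split groups the day 0 libraries as the one with 800 calls does and parts 1 pair of day 0 replicate numbers. The 3 other splits that part all 3 pairs at day 0, as the real one does, called 0, and with the replicate block the real split called 766. Of the 18 splits that part 1 pair, 1 called 846, 1 called 84 and the rest called 0. A count of 0 in the 3 splits therefore says little.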

How the results depend on the processing

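Leaving out the rRNA gene CT010467.1 was chosen only after the data were seen, as was repeating the lists and shared calls without day 0 Dox replicate 2. None of up to 437 named gene results reversed its sign under the alternatives run on it, nor did any of 105 list results with an estimated correlation, the block, RLE or library size alone. The named results were all calls in the main fit, so a reversal was unlikely from the start. Without day 0 Dox replicate 2 the median of the replication-dependent histones went from 2.2 to -0.073, and the cause of the changes below was not tested unless stated. The replicate block gave 313 calls at day 0 and 35 for day 3 minus day 0. DESeq2 gave 504 at day 0, 5 at day 3, 1286 at day 5, 115 for day 3 minus day 0, 321 for day 5 minus day 3 and 995 for day 5 minus day 0, and limma-voom 25 for day 3 minus day 0. Without a filter the counts were 549 at day 0, 25 at day 3, 203, 385 and 889 for the same differences. A day fitted alone gave 3 at day 0, 12 at day 3 and 1628 at day 5, and with the block 137, 98 and 2658. An absolute log2 fold change of at least 1, which can only lower a count, left 28 at day 0, 186 at day 5, 5, 54 and 144 for the differences, and 6925 and 5030 for the control contrasts. The rRNA gene left out gave 178 at day 0 and 845 at day 5. Leaving out 1 library gave 76 to 412 at day 0, 2 to 3 at day 3, 410 to 732 at day 5, 3 to 52, 45 to 155 and 308 to 795 for the differences, and 12666 to 12937 and 10715 to 11066 for the control contrasts; fewer libraries also lower the number of calls a test can make. Shared calls of day 0 and day 5 were 24 in the same and 46 in opposite directions with the block, and 8 and 14 without day 0 Dox replicate 2. The day 3 effect on genes that rose in the control course was 0.037 with the top 50 and 0.015 with the top 500, both no longer past the threshold. Of 437 named results, 3 calls ended with the block, 17 with limma-voom, 2 with RLE, 14 with library size alone and 4 without a filter, and 3 of 431 with DESeq2. The 437 include 145 and 140 from the control contrasts. With a day fitted alone 25 of 96 calls ended, and 3 of 96 with the block. Leaving out 1 library ended up to 26 of 67 among day 0 Dox libraries (replicate 2) and 44 of 119 among day 5 Dox libraries (replicate 3). Of 105 list results 24 calls ended with an estimated correlation. At a log2 change of 0.5 the fit recovered 52.2 to 55.2% of changes simulated at the fitted spread, so depth and spread limit small effects.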

Other observations

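All tests of the 7 lists below were chosen only after the result was seen; the test of a delay was not.

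As sets in camera, Hedgehog targets and ventral neural tube genes lay lower with Dox at day 5 and dorsal neural tube genes higher. Gli1, a transcription factor that Hedgehog signalling induces (chromosome 10, 127329882 to 127341974), fell from 16.9 ± 2.7 to 6.39 ± 1.7 CPM (SD, n = 3), with an edgeR adjusted p of 1e-05. Of 11 measured Hedgehog targets 5 fell and none rose, among them Pax1, Gli1 and Gas1, with a camera adjusted p of 2.83e-17, and adjusted p = 9.13e-05 with an estimated correlation. The fall was not shared by all members, as Ptch1 stood at 131 ± 13 CPM in control and 125 ± 2.8 CPM in Dox. The list does not separate genes that the pathway raises from any that it lowers. Its fall therefore does not give the direction of Hedgehog signalling. Pax1 is also on the somite list. Of 10 ventral neural tube genes 4 fell and none rose (Olig2, Olig1, Foxa2 and Nkx6-1), with a camera adjusted p of 2.73e-08, and adjusted p = 0.00186 with an estimated correlation. Dbx1, also on that list, stood at 367 ± 22 CPM in control and 358 ± 40 CPM in Dox. Some genes that fell had low levels, with Olig1 at 0.376 ± 0.14 CPM in control and 0.0497 ± 0.017 CPM in Dox. Of 13 dorsal neural tube genes 5 rose and none fell, among them Msx3, Gbx1, Pax3 and Pax7, with a camera adjusted p of 2.22e-07, and adjusted p = 0.0017 with an estimated correlation. Among 15 genes of retinoic acid metabolism and its targets Cyp26b1 and the binding protein Crabp1 rose, and those that fell included Dhrs3, Aldh1a2 and the receptors Rarg and Rarb. The camera adjusted p was 0.00266, and adjusted p = 0.0421 with an estimated correlation. At day 0 camera adjusted p was 0.089 for Hedgehog targets, of which 1 rose, 0.874 for ventral, 0.783 for dorsal and 0.783 for retinoic acid genes.

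Lysosome genes were lower with Dox at day 0 and higher at day 5. At day 0, 15 of 38 fell and none rose, among them Manba, Rragd and Ctsa, with a camera adjusted p of 2.29e-23, and adjusted p = 0.00909 with an estimated correlation. Without day 0 Dox replicate 2, 6 fell, with a camera adjusted p of 1.08e-20, and adjusted p = 0.0202 with an estimated correlation. At day 5, 5 of 38 rose and none fell (Gm2a, Tpp1, Rragd, Atp6v0d1 and Ppt1), with a camera adjusted p of 3.24e-11, and adjusted p = 0.0236 with an estimated correlation. At day 3 no edgeR call was made, with a camera adjusted p of 0.00196, and adjusted p = 0.671 with an estimated correlation. Of 18 cytosolic aminoacyl-tRNA synthetases 9 fell at day 5, such as Yars, Cars and Mars, with a camera adjusted p of 2.55e-10, and adjusted p = 0.039 with an estimated correlation. At day 0 Cars rose, with a camera adjusted p of 4.66e-09, and adjusted p = 0.145 with an estimated correlation. Of 25 ribosome biogenesis genes 10 fell at day 5, such as Utp20, Nop2 and Bop1, with a camera adjusted p of 5.81e-15, and adjusted p = 0.0205 with an estimated correlation.

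A delay of development with Dox at day 5 could lower genes that rise between day 3 and day 5 and raise those that fall. With 1 day 5 control library used for the course and the other 2 for the Dox effect, in 3 rotations, the median Dox effects of the risen genes were 0.068, 0.024 and 0.039 and those of the fallen genes 0.043, 0.063 and 0.029. Members of both sets moved in both directions. The camera adjusted p was 0.023 for the risen genes of the first rotation, which lay higher, and 0.55 to 0.89 for the other 5 sets, and it was 0.537 to 0.955 for the 6 sets with an estimated correlation. Set beforehand, a delay was to give a negative median of the risen genes and a positive one of the fallen genes in each rotation. The risen genes had a positive median in all 3 rotations, so that pattern was not met. The medians lay near 0 and no set passed with an estimated correlation, so a delay stays open.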
